A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

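The deposited files hold 1 table per library, with counts of reads over 50 bp bins of build R64 on 16 chromosomes. The submitters' processing notes name Bowtie2 for alignment, SAMtools for sorting and bedtools for coverage, without versions. Each table has 7 columns in the layout of bedtools coverage, and the column of counts was used. The last column, the fraction of each bin covered by reads, was made by the authors as deposited, by dividing covered bases by bin width, and entered no test. A read is counted in each bin it touches, so the bin counts exceed the number of reads, and summed windows are read as relative signal. The quasi-likelihood fit estimates the spread from the replicates and does not assume that counts are independent.

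The groups, the comparisons, the lists, the alternatives and the rule for naming origins were chosen before the data were examined; those chosen later are named as such. Of 241434 bins, 238182 were used. The 800 bins of the rDNA array (XII, 450 to 490 kb) were treated apart, and 2452 bins were left out because mean Total depth was under 0.4 or over 2 times the median. Total libraries give copy number in BrdU and hydroxyurea, so they also carry replicated DNA.

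No list of origins was at hand, since the reference held genes only. As laid down for that case, origins were taken as local maxima of IP over Total, averaged over the 10 IP groups and smoothed over 1050 bp. A maximum needed a ratio of at least 0.5, the highest value within 5 kb and a prominence of 1.25, and 6 maxima were dropped for low prominence. This gave 352 windows of 5 kb, which hold 14.4% of the usable bins; 22 of them have under 80 usable bins and lie mostly at repeat-rich chromosome ends. Maxima of the average over all strains were used, without regard to any contrast. A window weak in wild type could still pass through mutant groups where it was high. Origins without a maximum of their own are missing. Background bins lay more than 15 kb from any summit, which made 75231 bins (31.6%). Centromeres were placed in the gap between the genes of the arms, the widest gap being 2542 bp. Names of origins come from general knowledge of their positions; all 9 early reference origins and 3 of the 14 late ones had a summit within 2.5 kb.

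The test was edgeR's quasi-likelihood F test with robust estimation on IP counts per window, with 1 fit per experiment. The library size was the sum over usable bins, outside the rDNA array, and no further scaling factor was applied. A value therefore compares shares of single-copy BrdU; the data hold no spike-in, and an absolute amount cannot be had. Origins were called at a Benjamini-Hochberg adjusted p under 0.05 over the 352 windows of a comparison. Fold changes carry the standard error of the fit, and cpm values the SD between replicates. The interaction of experiments 1 and 2 used all 24 IP libraries in 1 fit. Measures per library were compared by exact permutation tests, two-sided.

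Per comparison the text names, among origins with an adjusted p under 0.05 and replicates that did not overlap, the 8 largest rises and the 8 largest falls. It also names the early and late reference origins, the array, and the genes RPD3, SIR2, FKH1, FKH2, FOB1 and BAR1. A name given by both parts of the rule counts under both. Fixed lists were the 9 early and 3 late reference origins, 33 origins within 20 kb of a centromere and 25 within 20 kb of a chromosome end. Windows at repeat-rich chromosome ends can share reads, so that list may hold fewer separate signals than windows. Its counts and p-values do not allow for this. Lists from one experiment were followed only in others: 183 origins that fell and 113 that rose in fkh1Δ fkh2-dsm, and 177 that rose and 100 that fell in rpd3Δ of experiment 1. Lists were tested with camera at its preset correlation, adjusted within a comparison, beside camera with an estimated correlation and fry. fry asks whether the origins of a list move one way on balance and compares them with no others. The lists of origins with forkhead motifs and of silent mating-type origins could not be formed, for want of a genome sequence and of matching summits.

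The method was tried on simulated counts at the depth and spread of these libraries. In experiment 1, 92% of 1.5-fold and 100% of 2-fold changes between wild type and rpd3Δ were recovered; in rDNA20 strains 70% and 96%, and for fkh1Δ fkh2-dsm 83% and 100%. Interactions gave 76% and 96% in experiment 1, 60% and 97% in experiment 3, and 67% and 94% between experiments 1 and 2. Among 152 unchanged windows 1 to 6 were called, and in runs with no change 0 to 3 of 352. The planted rises and falls were equal in number and library sizes were held fixed. These runs therefore do not address calls that move with the scaling.

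R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 was used, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.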

Results

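DNA synthesis at replication origins of budding yeast, Saccharomyces cerevisiae, was measured by BrdU-IP-seq. BrdU is a thymidine analogue that marks newly made DNA; DNA recovered with an antibody to it (IP) and DNA taken before that step (Total) were sequenced. The labels describe growth in YEPD at 23 °C, arrest in G1 with 5 nM α-factor for 4 h, and release into 400 µg/mL BrdU and 200 mM hydroxyurea. Hydroxyurea slows replication forks, so that most signal stays near the origins that fired. The 48 libraries, 24 IP and 24 Total, formed 10 strain groups, treated here as 3 experiments. The sample titles name no experiment. The commonest isolated reads were 36, 65 and 45 bp long in experiments 1, 2 and 3. Experiment 1 held wild type, rpd3Δ, sir2Δ and sir2Δ rpd3Δ, with 3 IP and 3 Total libraries each. Experiment 2 held a wild type and an rpd3Δ strain labelled rDNA20, with 2 and 2. Experiment 3 held wild type, rpd3Δ, fkh1Δ fkh2-dsm and libraries labelled fkh1Δ fkh2-dsm rpd3Δ, also with 2 and 2. The protocol gives harvests at 60 and 90 min, and the titles give 90 min only for wild type and rpd3Δ of experiment 3, so the harvest time of the other groups is not known. RPD3 encodes a histone deacetylase, SIR2 a deacetylase that acts in the ribosomal DNA (rDNA) array, and FKH1 and FKH2 encode forkhead transcription factors.

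The sum of counts over 50 bp bins lay between 1337447 and 8804888 per IP library and between 3150955 and 12047155 per Total library in experiment 1. The ranges were 2069958 to 4903435 and 4929890 to 11371790 in experiment 2, and 1305341 to 6390918 and 2970198 to 15075133 in experiment 3. A read is counted in each bin it touches, and isolated reads of IP libraries touched 1.91, 2.24 and 2.08 bins on average in the 3 experiments. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. Signal was summed in 352 windows of 5 kb centred on local maxima of IP over Total, called origins below, on build R64. Values are in cpm, counts scaled to the same single-copy nuclear IP total in each library, that is, shares: a rise at some origins must be met by a fall elsewhere. Names beginning with ARS are provisional, since they come from general knowledge and were matched to the nearest summit within 2.5 kb, with a largest distance of 1275 bp for the 9 early reference origins. Unless another figure is given, a list gave the same count when p-values were adjusted over the list alone.

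Depth of Total reads over the deleted genes was compared with the genotype labels. RPD3 (YNL330C, chromosome XIV 18001 to 19302) held 6.31% ± 0.157 of the genome median in rpd3Δ and 5.23% ± 0.918 in sir2Δ rpd3Δ (SD, n = 3). It held 5.54% ± 2.14 in rpd3Δ rDNA20 and 7.65% ± 1.75 in rpd3Δ at 90 min (n = 2). In the libraries labelled fkh1Δ fkh2-dsm rpd3Δ it held 150% ± 0.105, above the 104% ± 13.2 in fkh1Δ fkh2-dsm. The core of the reading frame in those libraries, at 18051 to 19150, stood at 0.936 and 1.01 times the genome median. The flank at 17701 to 18000 stood at 7.86 times and that at 19351 to 19600 at 8.07 times. Their IP libraries held 27 and 29 counts over the core, against 0 in each IP library of the other rpd3Δ groups. A scan of all 241434 bins found 2 regions raised in both of these Total libraries over wild type and rpd3Δ at 90 min, both at RPD3. The fkh1Δ fkh2-dsm libraries were not in that reference. The threshold lay above 2-fold at single-copy depth, so smaller gains could be missed. For that reason these libraries are named below by their label, and no statement on loss of RPD3 in the fkh1Δ fkh2-dsm background was drawn from them.

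The other genotypes could be read in the same way. SIR2 held 0.110% ± 0.190 of the genome median in sir2Δ and no count in sir2Δ rpd3Δ (n = 3). FKH1 held 0.971% ± 0.251 in fkh1Δ fkh2-dsm and no count in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ, while FKH2 stayed at 107% ± 9.46 and 119% ± 6.74 (n = 2). The labels do not explain the dsm allele, and the counts could not check it. FOB1, which the labels do not list as altered, held 1.05% ± 0.771 and 1.14% ± 0.349 in the wild type and rpd3Δ rDNA20 strains and 102% to 118% in the other groups. BAR1 held no count in experiments 1 and 3, and 115% ± 1.11 and 112% ± 15.2 in the rDNA20 strains. Where no count was seen, 3 counts would have been at most 1.07% of the median, a limit for counting error only.

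**Figure D1:**
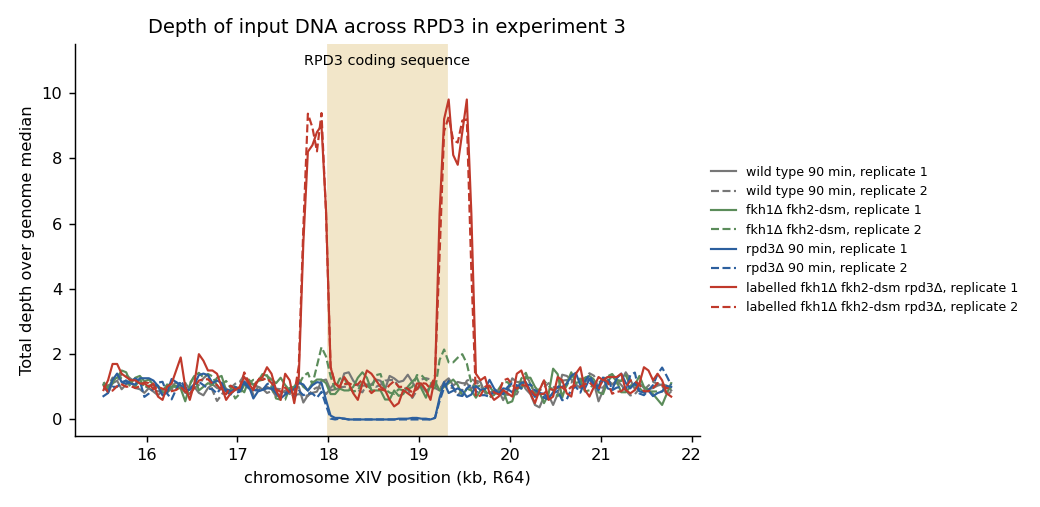
Total depth over RPD3 and its flanks (x axis, position on chromosome XIV; y axis, depth in multiples of the genome median), one line per Total library of experiment 3. The gene is missing in rpd3Δ at 90 min and stands near 0.973 in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ, whose flanks reach 7.86 and 8.07.

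The rDNA array was compared as IP over Total: the ratio of array to other counts in IP, divided by that in Total. This allows for array size but is relative to BrdU outside the array. Among the wild types of the 3 experiments it was lower where array depth was higher, so values are compared within experiments only. The ratio fell from 1.02 ± 0.0221 in wild type to 0.193 ± 0.00528 in rpd3Δ, 5.29-fold lower, and rose to 4.45 ± 0.196 in sir2Δ (SD, n = 3). In sir2Δ rpd3Δ it was 3.02 ± 0.173, or 0.679 times the sir2Δ value. The rDNA20 wild type stood at 6.60 ± 0.1 and its rpd3Δ strain at 3.42 ± 0.668, and in experiment 3 the values were 0.478 ± 0.00659 in wild type, 0.0910 ± 0.00191 in rpd3Δ and 0.160 ± 0.00253 in fkh1Δ fkh2-dsm (n = 2). The libraries labelled fkh1Δ fkh2-dsm rpd3Δ gave 0.147 ± 0.00626. Replicates did not overlap in any of these contrasts; the exact permutation p, two-sided, was 0.1 for 3 against 3 and 0.33333 for 2 against 2, the smallest each design allows. The array took 6.68% of IP counts in wild type, 1.31% in rpd3Δ, 20.9% in sir2Δ and 17.8% in sir2Δ rpd3Δ, and its Total depth stood at 47.9, 46.8, 40.2 and 48.5 times single-copy depth. In the rDNA20 strains that depth was 22.2 and 25.0, and in experiment 3 it lay between 92.7 and 103.

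**Figure D2:**
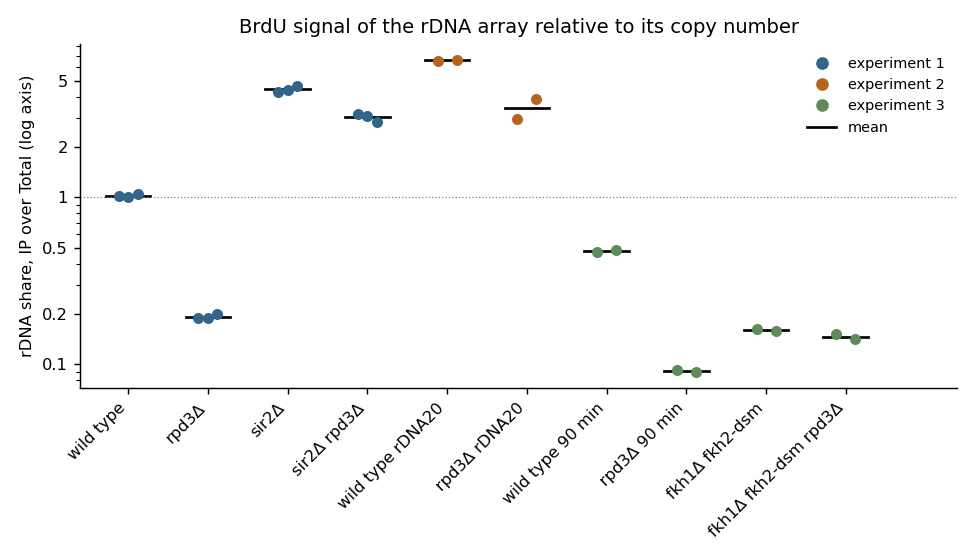
IP over Total in the rDNA array (y axis, log scale) for each replicate of the 10 strain groups (x axis), with group means. In each experiment rpd3Δ lies below its wild type, and sir2Δ lies above it.

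Wild type and rpd3Δ in experiment 1 address how loss of the deacetylase alters single-copy origins, the question in the series title. The origin over HO (chromosome IV 43926 to 48925, between SSB1 and GCS1) rose most, from 78.4 ± 11.1 to 684 ± 7.29 cpm (SD, n = 3), a log2 fold change of 3.13 (SE 0.18, adjusted p = 2.83e-11). The origin between SNR36 and GSP2 (XV 678526 to 683525) rose from 28.9 ± 7.81 to 223 ± 10.9 cpm, and that between the ribosomal protein genes RPS19B and RPL18B (XIV, 63 kb) from 107 ± 12.5 to 640 ± 21.3 cpm. The largest fall was over GNA1 (VI 101726 to 106725), from 598 ± 17.4 to 179 ± 4.75 cpm, a log2 fold change of -1.74 (SE 0.10). ARS305, between APA1 and YCL049C on chromosome III, fell from 7431 ± 369 to 4643 ± 110 cpm, a log2 fold change of -0.68 (SE 0.06, adjusted p = 5.26e-09).

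The 8 largest rises lay between 2.45 and 3.13 and included IV 139 kb (PCL9/DLD2), VAM6, HER1/MCP1, YJR124C and YHI9. The 8 largest falls also held the origin beside HSP104 (XII, 92 kb; -1.15), that beside COQ8 (VII, 286 kb; -1.02), MLH3, VHT1, JJJ3 and ADR1. Among the 9 early reference origins 7 fell, ARS306, ARS307, ARS315, ARS416, ARS606 and ARS607 by 0.56 to 0.68. ARS309 rose by 0.21 (SE 0.05) and ARS310 by 0.16 (SE 0.05), but with TMM factors they fell by 0.09 and 0.14, with background scaling by 0.10 and 0.15 and with DESeq2 by 0.12 and 0.18. Of the late ones, ARS603 in MIL1 rose from 66.9 ± 13.6 to 337 ± 29.6 cpm and ARS522 in DMC1 rose by 1.84 (SE 0.24), while ARS319 did not pass (-0.21, adjusted p = 0.346). By edgeR 277 origins changed, 177 up and 100 down, with 101 rises and 4 falls of at least 2-fold and a median SE of 0.11. Replicates did not overlap at 312 origins (88.6%, against 10% by chance), and 278 passed an unadjusted p of 0.05. With TMM factors 135 rose and 132 fell, and with DESeq2 132 rose and 142 fell; the median change of all origins was 0.24, and -0.06 and -0.10 with those factors. Among the 173 origins with IP over Total above 1.5, tested alone, 56 rose and 92 fell.

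Origins within 20 kb of a centromere fell at 25 of 33 and rose at 5 (camera adjusted p = 7.87e-07). Those within 20 kb of a chromosome end fell at 16 of 25 and rose at 4 (0.00718), and the early list gave 0.000853. None of these passed with an estimated correlation (adjusted p = 0.385 for the early and centromere lists and 0.402 for chromosome ends), and all 3 passed with fry (at most 0.000692). The 3 late origins gave 0.374. Origins were also ranked by wild type cpm in another experiment, in 4 classes of 88, a grouping chosen after the values were seen. In the strongest class 8 rose and 70 fell, then 51 and 23, 60 and 5, and in the weakest 58 and 2. Over all origins Spearman's rho was -0.60. Windows weak in wild type could pass the summit filter through mutant groups where they were high. That choice of windows favours rises in the weakest class.

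**Figure D3:**
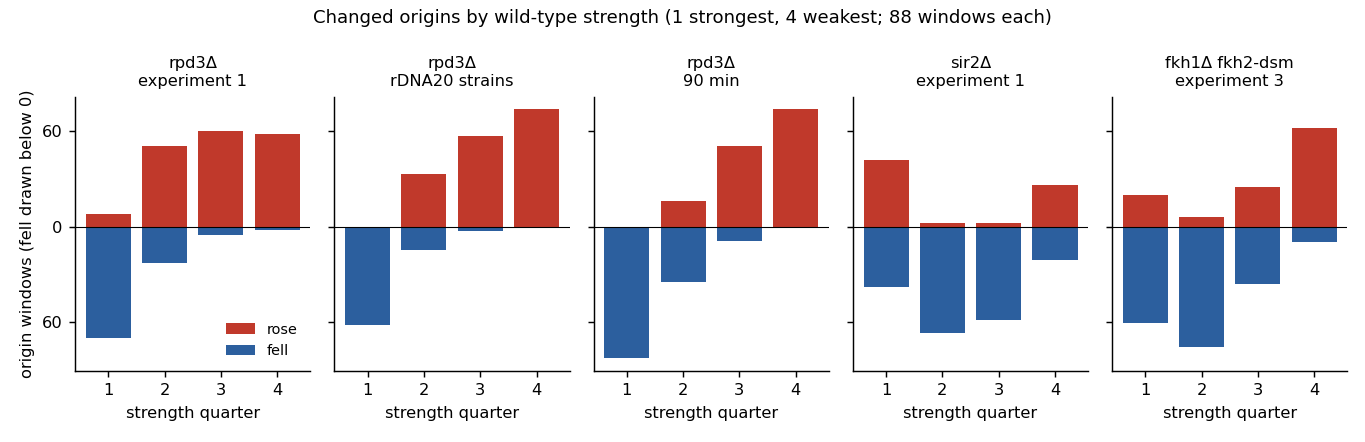
Number of origins that rose (drawn up) and fell (drawn down) in each of 4 classes of 88 origins ranked by wild type signal in another experiment (x axis, strongest first), for rpd3Δ in 3 experiments, sir2Δ and fkh1Δ fkh2-dsm. In rpd3Δ 70, 62 and 83 origins fell in the strongest class, and 58, 74 and 74 rose in the weakest. Windows were chosen on an average that includes these mutants, which favours rises in the weakest class.

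Wild type and sir2Δ address what the known rDNA regulator does at single-copy origins. From the strongest to the weakest of the 4 strength classes 42, 2, 2 and 26 origins rose and 38, 67, 59 and 21 fell, by classes chosen after the values had been seen. TOA2 (XI 327726 to 332725) fell from 2301 ± 81.6 to 378 ± 52.8 cpm (SD, n = 3), a log2 fold change of -2.62 (SE 0.10, adjusted p = 5.08e-14). The origin between ASG1 and TAO3 (IX 103326 to 108325) fell from 2513 ± 98.2 to 423 ± 25.2 cpm, and that between ATG1 and TOS3 by 2.58 (SE 0.12). ARS416, beside TRP1, fell from 4175 ± 62.3 to 1422 ± 67.7 cpm and ARS310 from 3071 ± 43.3 to 1120 ± 21.8 cpm. Total depth at TRP1 was 1.61 ± 0.0705 times the genome median in wild type and 1.84 ± 0.112 in sir2Δ. At URA3 it was 2.08 ± 0.232 and 1.04 ± 0.0857. The strains thus differ in more than SIR2, and the changes, the ARS416 fall among them, cannot be assigned to SIR2 alone. ARS305, ARS306, ARS307, ARS606 and ARS607 rose, by 0.58 to 0.76, and ARS607 went from 7331 ± 372 to 12127 ± 980 cpm. These early rises turned into falls at ARS305, ARS307, ARS315 and ARS606 under background scaling.

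The largest rises were at a chromosome end beside COS5 (X, 746 kb; 3.21, SE 0.27) and at the left end of chromosome III (2.32), windows with 49 and 51 usable bins. The other named rises lay between 1.08 and 1.17, over RQC2, RLF2, EAF7, NOP56 and SYH1 and between SNU66 and NOP58. ARS315 rose by 0.23 and ARS309 fell by 0.14 (adjusted p = 0.0274); that call was lost without wild type replicate 1 (-0.12) or without sir2Δ replicate 3 (-0.13), and ARS309 rose by 0.11 with TMM factors and by 0.32 with DESeq2. ARS319 (adjusted p = 0.0981), ARS522 (0.0730) and ARS603 (0.832) did not pass. By edgeR 257 origins changed, 72 up and 185 down, with 12 rises and 106 falls of at least 2-fold, and 263 did not overlap (74.7%, against 10% by chance). The split was 110 and 154 with TMM factors, 3 and 275 with background scaling and 144 and 135 with DESeq2; the median change was -0.42, and -0.17, -1.16 and 0.04 with those scalings. Near centromeres 19 of 33 rose and 6 fell (camera adjusted p = 9.15e-07), and near chromosome ends 4 of 25 rose and 3 fell (0.0200; 3 and 3 adjusted over the list alone). Both calls were lost with an estimated correlation (adjusted p = 0.567 for each); fry kept centromeres (0.00237) and lost chromosome ends (0.275). The early list gave 0.129 and the late list 0.430, where the median (0.06) and the mean (-0.03) differed in sign.

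**Figure D4:**
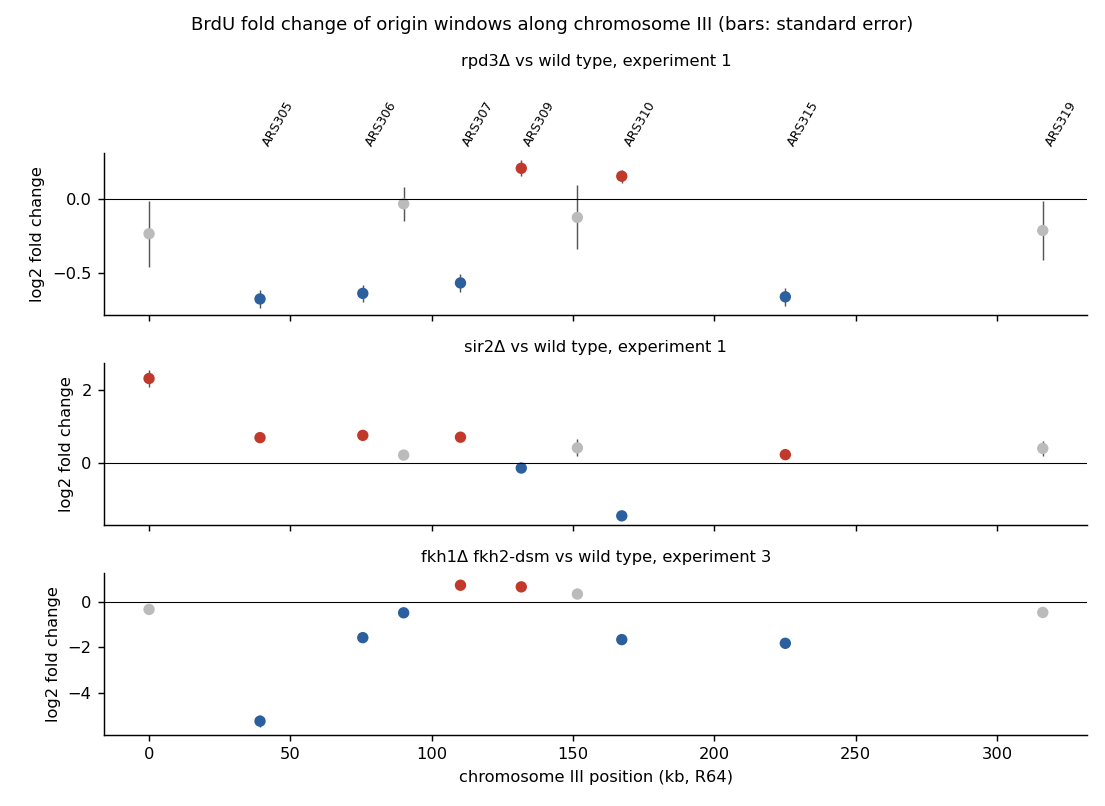
Log2 fold change of each origin on chromosome III (x axis, position in kb; bars, standard error) in rpd3Δ and sir2Δ of experiment 1 and in fkh1Δ fkh2-dsm of experiment 3, with the reference origins named. ARS305 rises by 0.70 in sir2Δ (but falls by 0.03 with background scaling) and falls by 5.25 in fkh1Δ fkh2-dsm.

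Wild type and sir2Δ rpd3Δ show both losses together. The origin beside COQ8 (VII 283876 to 288875) fell most, from 3782 ± 214 to 531 ± 32.9 cpm (SD, n = 3), a log2 fold change of -2.83 (SE 0.07, adjusted p = 2.24e-17). MLH3 (XVI, 241 kb) fell by 2.48 (SE 0.19) and the origin beside HSP104 from 4604 ± 238 to 927 ± 174 cpm. ARS416 fell by 1.28 (SE 0.06) and ARS310 by 0.41. Total depth at TRP1, beside ARS416, was 1.61 times the genome median in wild type and 2.10 in sir2Δ rpd3Δ. URA3 stood at 2.08 and 1.07 in the same strains. The changes, the ARS416 fall among them, therefore cannot be assigned to the named deletions alone. ARS305 was at 7159 ± 491 against 7431 ± 369 cpm, a change of -0.05 (SE 0.06, adjusted p = 0.476).

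ARS306, ARS307, ARS315, ARS606, ARS607 and ARS522 did not pass either; ARS309 rose by 0.25 (but fell by 0.26 with background scaling), ARS319 by 0.64 (adjusted p = 0.0122) and ARS603 by 0.80 (SE 0.22). Rises were largest beside COS5 (2.26), beside the rDNA array (XII, 450 kb; 2.01, 51 usable bins), over HO (1.54) and between SED5 and AAT2 (1.41), with YJR124C, the left end of chromosome III, MAL33/MAL31 and MPD2 at 1.15 to 1.37. The other large falls, by 1.78 to 2.00, lay beside ZPS1, ECM23, RGI2 and VHT1 and over MLG1. By edgeR 181 origins changed, 69 up and 112 down, and 195 did not overlap (55.4%, against 10% by chance). With background scaling 13 rose and 228 fell, at a median change of -0.61 against -0.07. No list passed with camera: adjusted p was 0.603 for the early list and 0.404 for the late, centromere and chromosome end lists. The centromere list, with 6 up and 8 down, had a negative median (-0.01) and the chromosome end list, with 6 up and 3 down, a median of -0.09 and a mean of 0.12, while camera ranked both above the other origins.

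The sir2Δ and sir2Δ rpd3Δ strains show the loss of Rpd3 where SIR2 was already absent. HO rose from 38.0 ± 12.2 to 227 ± 50.9 cpm (SD, n = 3), a log2 fold change of 2.59 (SE 0.20, adjusted p = 7.56e-10). MPD2 (XV 151476 to 156475) rose by 2.49 (SE 0.19), YJR124C by 2.47 (SE 0.14) and NNF2, beside CTT1, from 147 ± 13.0 to 774 ± 55.0 cpm. The origin beside HSP104 fell from 3170 ± 271 to 927 ± 174 cpm and ARS305 from 12032 ± 687 to 7159 ± 491 cpm. ARS310 rose from 1120 ± 21.8 to 2313 ± 70.0 cpm, a change of 1.05 (SE 0.05).

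The other large rises lay beside MKK2 and SED5, over YDC1 and beside YVC1 (2.07 to 2.26), and the other large falls beside COQ8 (-1.51), over GNA1, beside SHE4, at the left end of chromosome III, over JJJ3, beside COS5 and over ADR1 (-0.93). ARS306, ARS307, ARS606 and ARS607 fell by 0.64 to 0.79 and ARS315 by 0.30 (but rose by 0.0418 with 10 kb windows); ARS309 rose by 0.39, ARS416 by 0.28 (but fell by 0.0871 with DESeq2) and ARS603 by 0.74, while ARS319 (adjusted p = 0.301) and ARS522 (0.631) did not pass. By edgeR 242 origins changed, 168 up and 74 down, with 62 rises and 5 falls of at least 2-fold, and 242 did not overlap (68.8%, against 10% by chance). The split was 138 and 105 with TMM factors, 184 and 19 with background scaling and 108 and 137 with DESeq2; the median change was 0.28, and 0.13, 0.49 and -0.08 with those scalings. Near centromeres 24 of 33 fell and 7 rose (camera adjusted p = 5.61e-06; adjusted p = 0.670 with an estimated correlation). The early list, 3 up and 6 down, gave 0.0562, chromosome ends, 4 up and 5 down, 0.134, and the late list, 1 up and none down, 0.945, ranked below the other origins although its median was 0.24.

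The rpd3Δ effect with SIR2 deleted was tested against that with SIR2 present as an interaction. These backgrounds also differ in Total depth at URA3, so a difference cannot be assigned to SIR2 alone. The rpd3Δ effect differed at 175 origins by edgeR, 93 with a higher and 82 with a lower log2 fold change in the sir2Δ background. By the same test 203 passed an unadjusted p of 0.05. The split was 118 and 71 with TMM factors, 129 and 43 with background scaling, 75 and 92 with DESeq2 and 64 and 75 with Total as offset, so the larger side turned with the latter pair; the median difference was 0.01, and 0.16, 0.53, -0.02 and -0.02 with those settings. Among the 173 origins with IP over Total above 1.5, tested alone, 91 were higher and 6 lower, and without sir2Δ replicate 3 the split was 90 and 92. The origin between ASG1 and TAO3 differed by 1.38 (SE 0.09) and BOI1 (II, 64 kb) by 1.32 (SE 0.08). The origin between SNR36 and GSP2 differed by -3.05 (SE 0.39) and PRP3 (IV, 1405 kb) by -2.53 (SE 0.30); these 4 were named after their values were seen. Across origins, which are not independent replicates, the effects had a Pearson correlation of 0.66 and a Spearman correlation of 0.71 (0.87 and 0.91 over the 206 origins with IP over Total above 1.5), among 9 pairs of effects computed.

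The rDNA20 wild type and rpd3Δ strains put the same deletion into cells with fewer rDNA copies, as the Total depth shows. Unlike those of experiment 1, these cells also lack FOB1 and hold BAR1. RRN11 and CAT2 stood at 1.96 and 2.12 times the genome median in Total of the rDNA20 wild type. In its rpd3Δ strain they stood at 0.956 and 1.04. This pair of strains thus differs outside RPD3 too, and the changes cannot be assigned to RPD3 alone. HO rose from 82.2 ± 1.48 to 727 ± 10.0 cpm (SD, n = 2), a log2 fold change of 3.15 (SE 0.23, adjusted p = 2.01e-36). SNR36/GSP2 rose by 3.14 (SE 0.32), SEC2 beside TOF1 (XIV 124426 to 129425) by 2.96 (SE 0.28) and SRP68 (XVI, 90 kb) from 76.6 to 561 ± 40.0 cpm. The origin beside HSP104 fell from 2655 ± 33.0 to 464 ± 141 cpm, and ARS305 from 7280 ± 90.8 to 3056 ± 693 cpm. ARS522 rose by 2.16 (SE 0.27) and ARS603 from 45.3 ± 3.73 to 263 ± 24.0 cpm.

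The other large rises, 2.77 to 2.84, lay over ZWF1, DML1 and HFL1 and beside SUP7; the other large falls lay over JJJ3 (-1.60), DCG1 (-1.48) and beside NFG1, IFM1, HHF1, NOP9 and MET5 (-1.29 to -1.32). ARS306, ARS307, ARS416, ARS606 and ARS607 fell by 1.02 to 1.27, and ARS309, ARS310, ARS315 and ARS319 did not pass (adjusted p = 0.618 to 0.949). By edgeR 244 origins changed, 164 up and 80 down, with 134 rises and 38 falls of at least 2-fold and a median SE of 0.25; 295 did not overlap (83.8%, against 33.3% by chance). Without wild type rDNA20 replicate 1 the count was 136 (132 up, 4 down) and without replicate 2 it was 130 (126 up, 4 down), and either omission ended the calls on ARS305 (-1.27, -1.24), ARS306, ARS307, ARS416, ARS606, ARS607 and the falls beside NFG1, IFM1, HHF1, NOP9 and MET5. With background scaling 11 origins changed; with TMM factors 145 rose and 110 fell, and with DESeq2 135 and 115. Among the 165 origins with IP over Total above 1.5, tested alone, 20 rose and 69 fell. The median change was 0.36, and 0.11 with TMM factors, -0.73 with background scaling and 0.00 with DESeq2. Near centromeres 25 of 33 fell and 3 rose (camera adjusted p = 1.27e-08); near chromosome ends 13 of 25 fell and 3 rose and in the early list 6 fell (both 0.00103). These 3 lists gave adjusted p = 0.361 with an estimated correlation, and the late list, 2 up, gave 0.218 with camera.

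The rDNA20 and experiment 1 effects were set against each other in an interaction over all 24 IP libraries. It differed at 108 origins by edgeR, 47 with a higher and 61 with a lower log2 fold change in the rDNA20 strains, and 137 passed an unadjusted p of 0.05. MLH3 (XVI, 241 kb) differed by 2.11 (SE 0.23), GNA1 by 1.86 (SE 0.17) and the origin beside HSP104 by -1.37 (SE 0.21), all named after their values were seen. With TMM factors 34 were higher and 102 lower, with background scaling 7 and 103, and with DESeq2 40 and 97; the median difference moved from 0.03 to -0.16, -0.74 and -0.11. Among origins with IP over Total above 1.5, tested alone, 8 were higher and 62 lower. The count was 52 (32 higher, 20 lower) and 45 (24, 21) without wild type rDNA20 replicate 1 or 2, 40 (32, 8) without rpd3Δ rDNA20 replicate 1 and 135 (40, 95) without its replicate 2, so the larger side turned with 1 library. Experiment, FOB1, BAR1, rDNA size and read length differ together here, so the count cannot be assigned to one of them.

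The 177 origins that rose and the 100 that fell in rpd3Δ in experiment 1 were followed in the other experiments. The windows were chosen on an average that includes the rpd3Δ groups of these experiments, which favours rises of weak windows in each. The counts and correlations below are therefore not a fully independent repeat. In rDNA20 strains 146 of the 177 rose and 1 fell (camera adjusted p = 1.83e-43), and of the 100, 74 fell and 4 rose (1.34e-35; 76 and 4 adjusted over the list alone). At 90 min 121 rose and 13 fell, and 94 fell and 1 rose. With an estimated correlation the rDNA20 lists gave adjusted p = 0.0946 and 0.164, and the 90 min lists gave adjusted p = 0.0687 with an estimated correlation. Across 352 origins the experiment 1 effects correlated with those in rDNA20 strains at 0.89 (Spearman 0.89) and with those at 90 min at 0.83 (0.85), and the latter pair at 0.90 (0.92). The effect in sir2Δ cells correlated with the rDNA20 effect at 0.54 and with the 90 min effect at 0.40, and at 0.81 and 0.67 over the 206 origins with IP over Total above 1.5, where the 3 pairs before gave 0.93, 0.84 and 0.88.

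**Figure D5:**
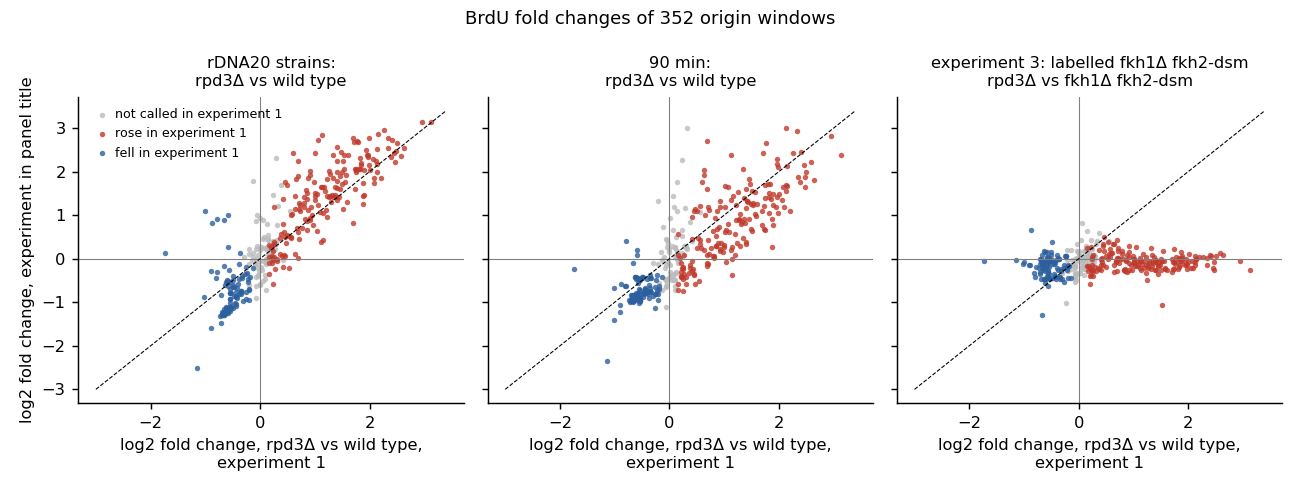
Log2 fold change of each of the 352 origins in rpd3Δ over wild type of experiment 1 (x axes) against rpd3Δ in rDNA20 strains, rpd3Δ at 90 min, and libraries labelled fkh1Δ fkh2-dsm rpd3Δ over fkh1Δ fkh2-dsm (y axes, one panel each; dashed line, equal change). Pearson correlations are 0.89 and 0.83 in the first panels, and in the last a line through the 277 origins called in experiment 1 has a slope of 0.0406. Windows were chosen on an average that includes the rpd3Δ groups, which favours rises of weak windows in each experiment.

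Wild type and rpd3Δ at 90 min repeat the deletion in the experiment with the forkhead alleles. PRP3 (IV 1402276 to 1407275, between TRS31 and JIP4) rose from 41.0 ± 6.60 to 325 ± 21.3 cpm (SD, n = 2), a log2 fold change of 3.01 (SE 0.20, adjusted p = 3.14e-08). YRB30, beside RAD54 (VII, 192 kb), rose by 3.00 (SE 0.27) and ARS603 from 62.3 ± 17.1 to 465 ± 9.98 cpm. The origin beside HSP104 fell from 4485 ± 13.8 to 884 ± 25.3 cpm and that beside COQ8 from 3786 ± 74.4 to 1426 ± 71.4 cpm. ARS305 fell from 7143 ± 160 to 3728 ± 116 cpm, a log2 fold change of -0.94 (SE 0.23).

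The other large rises, 2.44 to 2.81, lay beside SNR36 and CRC1 and over NOP7, APL5 and SEC2, and the other large falls, by 1.00 to 1.22, over JJJ3 and DCG1 and beside BEM1, VHT1, ZPS1 and a pair of tRNA genes at VIII 133 kb. ARS306, ARS307, ARS310, ARS315, ARS416, ARS606 and ARS607 fell by 0.58 to 0.99; the calls on ARS307 (-0.75) and ARS310 (-0.53) were lost without rpd3Δ 90 min replicate 2. ARS309 did not pass (-0.30, adjusted p = 0.129), while ARS319 rose by 1.32 and ARS522 by 1.70. By edgeR 269 origins changed, 141 up and 128 down, with 92 rises and 8 falls of at least 2-fold, and 333 did not overlap (94.6%, against 33.3% by chance). With background scaling 46 rose and 237 fell (median change -0.99, against 0.09), and with DESeq2 117 and 171 (-0.22). Among the 195 origins with IP over Total above 1.5, tested alone, 35 rose and 120 fell. Near centromeres 27 of 33 fell and 2 rose (camera adjusted p = 2.55e-05), near chromosome ends 18 of 25 fell and 4 rose (0.0166; 18 and 5 adjusted over the list alone), in the early list 8 fell (0.00512) and in the late list all 3 rose (0.0166). None passed with an estimated correlation (adjusted p = 0.338 for the first 3 lists and 0.269 for the late list). All 4 passed with fry (0.000665 to 0.0295), and with TMM factors all but chromosome ends (0.0899) did.

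Wild type and fkh1Δ fkh2-dsm address which origins need the forkhead factors. Since only the wild type carries a harvest time in its title, a difference in that time cannot be excluded. CUP1-1, a gene in a tandem array, stood at 6.87 ± 0.398 times the genome median in Total of wild type and at 2.08 ± 0.0580 in fkh1Δ fkh2-dsm. The strains thus differ outside FKH1 and FKH2 too, and the changes cannot be assigned to the forkhead alleles alone. ARS305 (III 36826 to 41825) fell from 7143 ± 160 to 186 ± 63.0 cpm (SD, n = 2), 38.1-fold, a log2 fold change of -5.25 (SE 0.28, adjusted p = 1.94e-10). TOR2 (XI 53476 to 58475) fell from 6062 ± 253 to 318 ± 59.5 cpm and the origin between RDR1 and FRE3 (XV, 1053 kb) by 4.00 (SE 0.22). LCD1 (IV 1445526 to 1450525) rose from 76.3 ± 43.0 to 1180 ± 141 cpm, a log2 fold change of 4.01 (SE 0.31), and RPC19 (XIV, 413 kb) from 168 ± 66.2 to 2002 ± 199 cpm. ARS607 fell by 2.26, ARS315 by 1.82, ARS310 by 1.66 and ARS306 by 1.57.

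The other large rises, 3.32 to 3.99, lay beside ASP1, MIN6, SFP1, SNR36 and USV1 and over PRP3. The other large falls lay beside NGL3 (-3.77) and at 4 repeat-rich chromosome ends (-3.67 to -3.70). Such ends can share reads, so the 25 windows of the chromosome end list may hold fewer separate signals. ARS309 rose by 0.67, ARS603 by 2.05, ARS307 by 0.74 and ARS522 by 0.69; the ARS307 call was lost without wild type 90 min replicate 2 (0.71) or fkh1Δ fkh2-dsm replicate 2 (0.67), the ARS522 call without the latter (0.54), and ARS307, ARS309 and ARS522 fell with background scaling, by 0.26, 0.34 and 0.31. ARS319 (adjusted p = 0.0597), ARS416 (0.939) and ARS606 (0.0707) did not pass. By edgeR 296 origins changed, 113 up and 183 down, with 68 rises and 135 falls of at least 2-fold, and 327 did not overlap (92.9%, against 33.3% by chance). The split was 180 and 131 with TMM factors, 47 and 243 with background scaling and 155 and 156 with DESeq2; the median change was -0.47, and 0.36, -1.48 and -0.06 with those scalings. Near chromosome ends 21 of 25 fell and none rose, at a median of -3.46 (camera adjusted p = 5.67e-11), and near centromeres 23 of 33 rose and 3 fell (0.00143; 22 and 2 adjusted over the list alone). Neither passed with an estimated correlation (adjusted p = 0.157 and 0.620), but both did with fry (4.03e-06 and 0.0421) and with TMM factors (6.56e-08 and 4.32e-06). The early list, 2 up and 5 down, gave 0.470 and the late list, 2 up, 0.306.

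The origins that changed in fkh1Δ fkh2-dsm were followed in the rpd3Δ comparisons of the other experiments. The windows were chosen on an average that includes both kinds of mutant, so these comparisons are not fully independent. Of the 113 that rose, 79 rose and 17 fell in rpd3Δ of experiment 1 (camera adjusted p = 0.00154) and 79 rose and 16 fell in rDNA20 strains (1.65e-06). Of the 183 that fell, 76 rose and 75 fell in experiment 1 and 60 and 57 in rDNA20 strains; camera ranked them below the other origins (0.00154 and 1.65e-06) although their mean was 0.15 and 0.12 (median 0.0381 and -0.0237). With an estimated correlation adjusted p = 0.256 for both lists in experiment 1, and 0.406 and 0.0946 in rDNA20 strains. In sir2Δ rpd3Δ over sir2Δ neither list passed (0.155 for each), and the 113 were ranked below the others although their median was 0.14. The 177 origins that rose in rpd3Δ held 79 rises and 76 falls in fkh1Δ fkh2-dsm (6.00e-07) and the 100 that fell held 17 and 75 (1.89e-10; adjusted p = 0.334 for both with an estimated correlation). Effects of rpd3Δ in experiment 1 and of fkh1Δ fkh2-dsm correlated at 0.52 (Spearman 0.50), those in rDNA20 strains at 0.54, and those of sir2Δ at 0.19; over the 206 origins with IP over Total above 1.5 the values were 0.29, 0.27 and 0.0321.

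The libraries labelled fkh1Δ fkh2-dsm rpd3Δ, which held RPD3 at full depth, were compared with wild type at 90 min. CUP1-1 stood at 1.83 ± 0.0372 times the genome median in their Total and at 6.87 ± 0.398 in wild type. The strains thus differ outside the named alleles, and the harvest time of the labelled libraries is not known. ARS305 fell from 7143 ± 160 to 79.4 ± 27.5 cpm (SD, n = 2), 92.8-fold, a log2 fold change of -6.54 (SE 0.30, adjusted p = 2.99e-11). TOR2 fell to 220 ± 22.2 cpm and the origin between MAL33 and MAL31 (II 799776 to 804775) from 658 ± 12.2 to 32.6 ± 2.23 cpm. LCD1 rose to 1130 ± 250 cpm and RPC19 to 1958 ± 443 cpm. The other large rises lay between 3.19 and 3.91 and the other large falls between -3.81 and -4.55.

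ARS306, ARS310, ARS315 and ARS607 fell by 1.40 to 2.39, ARS603 rose by 1.89 and ARS522 by 0.69 (but fell by 0.41 with background scaling). ARS319 fell by 0.49 (adjusted p = 0.0360), a call lost without wild type 90 min replicate 1 (-0.45) or 2 (-0.53) or fkh1Δ fkh2-dsm rpd3Δ replicate 2 (-0.35), and it rose by 0.39 with TMM factors. ARS307, ARS309, ARS416 and ARS606 did not pass. By edgeR 277 origins changed, 95 up and 182 down, and 301 did not overlap (85.5%, against 33.3% by chance). The split was 180 and 130 with TMM factors, 44 and 270 with background scaling and 160 and 162 with DESeq2; the median change was -0.48, and 0.41, -1.59 and -0.01 with those scalings. Near chromosome ends 23 of 25 fell (median -3.49, camera adjusted p = 1.02e-10) and near centromeres 6 of 33 rose and 3 fell (0.0290). Neither passed with an estimated correlation (adjusted p = 0.288 and 0.698); with fry chromosome ends passed (2.08e-05) and centromeres did not (0.431), and with TMM factors both passed (1.24e-07 and 0.000566). The early list gave 0.310 and the late list 0.302.

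The same libraries were compared with fkh1Δ fkh2-dsm. ARS305 fell from 186 ± 63.0 to 79.4 ± 27.5 cpm (SD, n = 2), a log2 fold change of -1.28 (SE 0.26, adjusted p = 0.0385). The origin between MAL33 and MAL31 fell from 69.1 ± 0.798 to 32.6 ± 2.23 cpm (SE 0.17, adjusted p = 0.00548). HO, SNR36/GSP2, PRP3 and the origin beside HSP104 did not pass, and neither did the other early and late reference origins, whose changes lay between -0.57 and 0.18. By edgeR these 2 origins changed and 26 passed an unadjusted p of 0.05, while DESeq2 called 30, 3 up and 27 down. The count was 0 without fkh1Δ fkh2-dsm replicate 2 (ARS305 -0.88, MAL33/MAL31 -1.05), 206 (27 up, 179 down) without fkh1Δ fkh2-dsm rpd3Δ replicate 2 and 16 (7 up, 9 down) without its replicate 1. Replicates did not overlap at 109 origins (31.0%, against 33.3% by chance). Origins near centromeres had a median change of -0.42, none of the 33 being called (camera adjusted p = 2.63e-09), and the early list, with 1 called (2 adjusted over the list alone), gave 0.00678; adjusted p = 0.569 for both with an estimated correlation. The late list (0.784) and chromosome ends (0.626, with 1 called, 2 adjusted over the list alone) did not pass, and for both the median (-0.03) was negative while camera ranked them above the others. Of the 177 and 100 origins that rose and fell in rpd3Δ in experiment 1, 1 each fell here (0.393, with a negative median of -0.07 and an upward rank, and 0.000516; adjusted p = 0.860 for the latter with an estimated correlation).

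The change from fkh1Δ fkh2-dsm to these libraries was tested against the rpd3Δ effect at 90 min as an interaction. By edgeR 161 origins differed, 43 higher and 118 lower in the forkhead background, and 201 passed an unadjusted p of 0.05. PRP3 differed by -3.09 (SE 0.27), ARS603 by -3.08 (SE 0.32) and the origin beside HSP104 by 2.31 (SE 0.23), named after their values were seen. The split was 88 and 128 with TMM factors, 201 and 42 with background scaling and 152 and 98 with DESeq2, and the median difference was -0.14, and -0.14, 0.84 and 0.22 with those scalings. Among origins with IP over Total above 1.5, tested alone, 42 were higher and 30 lower. The count was 263 (125 higher, 138 lower) without fkh1Δ fkh2-dsm rpd3Δ replicate 1 and 117 (10, 107) without fkh1Δ fkh2-dsm replicate 1.

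The share of single-copy IP counts inside the 352 windows measured how far signal gathered at origins. It was 61.9% ± 1.27 in wild type, 56.0% ± 0.414 in rpd3Δ, 63.3% ± 2.46 in sir2Δ and 53.8% ± 2.03 in sir2Δ rpd3Δ (SD, n = 3). In rDNA20 strains it was 49.8% ± 0.414 and 36.7% ± 6.26, and in experiment 3 65.6% ± 0.242 in wild type, 49.8% ± 1.82 in rpd3Δ, 43.8% ± 2.51 in fkh1Δ fkh2-dsm and 36.9% ± 8.21 in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ (n = 2). The number of origins that together held 50% of that signal rose with rpd3Δ, from 46 to 63.7 in experiment 1, from 42.5 to 74.5 in rDNA20 strains and from 58.5 to 82 in experiment 3, and fell to 28 in sir2Δ and 30 in fkh1Δ fkh2-dsm. In sir2Δ rpd3Δ it was 40.7, above sir2Δ but below wild type. In the libraries labelled fkh1Δ fkh2-dsm rpd3Δ it was 36.5, also below wild type. Around the early reference origins, 40.8% ± 1.28 of signal within 10 kb lay more than 2.5 kb away in wild type, 47.1% ± 0.520 in rpd3Δ, 34.7% ± 1.10 in sir2Δ and 47.0% ± 1.14 in sir2Δ rpd3Δ (n = 3). In rDNA20 strains that share was 48.4% ± 0.349 and 59.6% ± 4.21, and in experiment 3 34.0% ± 0.151 in wild type, 47.9% ± 1.83 in rpd3Δ, 55.2% ± 2.29 in fkh1Δ fkh2-dsm and 61.7% ± 8.33 in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ (n = 2). Replicates did not overlap in these contrasts, at the smallest exact p the design allows, except for the share in windows of sir2Δ and wild type (exact permutation p = 0.4) and for both measures in fkh1Δ fkh2-dsm and the libraries labelled fkh1Δ fkh2-dsm rpd3Δ.

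Total depth at the early reference origins over background measured how far they had been copied. It was 1.4998 ± 0.0671 in wild type, 1.36 ± 0.0341 in rpd3Δ, 1.39 ± 0.0705 in sir2Δ and 1.35 ± 0.0824 in sir2Δ rpd3Δ (SD, n = 3), and replicates overlapped in these contrasts except for rpd3Δ and wild type. In rDNA20 strains it was 1.4954 ± 0.000304 in wild type and 1.64 ± 0.0289 in rpd3Δ. In experiment 3 it was 1.51 ± 0.0192 in wild type, 1.68 ± 0.0212 in rpd3Δ, 1.27 ± 0.00114 in fkh1Δ fkh2-dsm and 1.33 ± 0.0434 in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ (n = 2), and no replicates overlapped in the contrasts of these 2 experiments (exact permutation p = 0.33333).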

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

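The test of forks spreading into weak windows was laid down before its result was seen; the other tests below were chosen after the result was seen.

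Interaction terms in edgeR set the change between libraries labelled with and without rpd3Δ in one background against that in another. That change differed at 175 origins between cells with and without SIR2, at 108 between rDNA20 strains and experiment 1, and at 161 between the strains of experiment 3 with and without the forkhead alleles. For the SIR2 interaction, 2 of 100 splits of the libraries, the real one included, gave as many origins, and the highest other split gave 204. That split exchanged the rpd3Δ labels of 4 sir2Δ libraries and of none with SIR2. Exchanged labels turn the rpd3Δ effect itself, of 277 and 242 origins, into spread or into a difference between backgrounds. The splits therefore do not decide whether chance can be excluded. URA3 in Total stood at 2.08 and 1.98 times the genome median in wild type and rpd3Δ. With SIR2 deleted it stood at 1.04 and 1.07, so the 175 cannot be assigned to SIR2 alone. The 108 cannot be told apart from a difference between experiments, since FOB1, BAR1, rDNA size and read length change together. The 161 rest on libraries that held RPD3, so no loss of RPD3 was measured there. They also rest on groups whose harvest time the labels do not give. CUP1-1 stood at 2.08 and 1.83 times the genome median in those groups and at 6.87 in wild type at 90 min, so strain background differs too. For the 4 comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05: only 1 split, the real one, gave as many in each, with 277, 257, 181 and 242 origins and a highest other of 0.

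A signal outside the main measurement lay in the Total libraries labelled fkh1Δ fkh2-dsm rpd3Δ, whose RPD3 flanks stood at 7.86 and 8.07 times the genome median. The reading frame between them was at 0.973 times the median. A swap with the fkh1Δ fkh2-dsm libraries is argued against, since these held RPD3 at no less than 0.949 and would have to lack it. Their flanks stood at 1.60 and 1.69 in replicate 2 and at 1.09 and 0.967 in replicate 1. Some mixing between these samples is therefore not excluded, and was not tested. A construct marked with URA3, TRP1, LEU2, HIS3, LYS2 or ADE2 is argued against too: the highest marker ratio was 1.245, at HIS3, far under the flank depth. An intact RPD3 gene in the sequenced cells goes with the IP libraries, the lower of which held 27 counts over the core. The raised flanks ended where depth changed in rpd3Δ at 90 min. At 17951 to 18050 replicate 1 went from 6.4 to 1.6, and rpd3Δ replicate 1 from 0.595 to 0.119. At 19151 to 19250 they went from 1.3 to 6.3 and from 0.0476 to 0.667. A construct that carries these flanks, with a marker that the reference lacks, goes with those edges but was not tested. A strain mix-up outside these samples would not by itself account for the raised flanks, and was not tested either.

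Between these libraries and fkh1Δ fkh2-dsm 2 origins changed, and the slope of the change on the rpd3Δ effects of experiment 1 was 0.0406 over 277 origins, against 0.910 for rpd3Δ at 90 min. Spread between replicates that hides an effect as large as in wild type is argued against by that slope, which was 0.0499 without replicate 1 and 0.0282 without replicate 2. RPD3 still being present would give a slope near 0 and so would an effect that needs Fkh1 or Fkh2. The 0.0499 alone cannot tell them apart. RPD3 reads were present in these libraries, at 0.936 and 1.01 times the genome median over the core in Total. Loss of RPD3 without Fkh1 was therefore not measured. A need for Fkh1 or Fkh2 was not tested, since 0 groups lack both RPD3 and FKH1. The biological explanation in the series title is therefore neither supported nor excluded by these libraries.

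In rpd3Δ strong origins fell and weak ones rose as shares of single-copy BrdU. The windows were chosen on an average that includes the rpd3Δ groups, which favours rises among weak ones. No set of windows chosen without the rpd3Δ libraries was tested. How much of the weak rises comes from that choice is therefore not known, and the tests below use the same windows. One factor common to all origins is argued against in experiment 1 and at 90 min: with background scaling 45.8% of 227 and 16.3% of 283 called origins were still on the smaller side. In rDNA20 strains that scaling left 11 calls, 8 up and 3 down. There such a factor is argued against by the share of origin signal in the weaker windows with background removed, which it would leave alike: 14.8% in the lowest rpd3Δ library and 5.67% in the highest wild type library. A higher even background is argued against as well, since with background removed the weaker origins took 9.98% of origin signal in the lowest rpd3Δ library and 4.54% in the highest wild type library of experiment 1, and 17.8% and 7.75% at 90 min. Forks spreading from strong origins are argued against by weak windows with no summit within 15 kb, whose median change was 1.04 times or more that of windows with one, in all 3 experiments. Total depth at the early reference origins over background, which is not a share of BrdU, moved both ways with rpd3Δ. It fell from 1.4998 to 1.36 in experiment 1. It rose from 1.4954 to 1.64 in rDNA20 strains and from 1.51 to 1.68 at 90 min. A lower copy number, which less firing of early origins would give, was thus seen in experiment 1 only. A redistribution of initiation towards weaker origins after loss of Rpd3 may remain as a hypothesis. It was found and tested on the same data, in windows chosen partly on rpd3Δ signal. A slower or longer S phase in rpd3Δ was not tested. No value here decides between redistribution and such an S phase. That needs amounts of BrdU per origin against a spike-in, at several harvest times of each strain.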

How the results depend on the processing

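Counts divided by bins per read (1.75, 2.33 and 1.88 in the 3 experiments, from the commonest read lengths), the removal of repeat-rich windows, strength classes, background-removed shares, the scan around RPD3 and fits without the libraries labelled fkh1Δ fkh2-dsm rpd3Δ were chosen after seeing the data; the other alternatives were planned. Where a value changed, the cause was not tested unless one is given. Below, rpd3Δ/WT and the like name comparisons, with the experiment as 1, 2 or 3, and fkh and fkhrpd3 stand for the libraries labelled fkh1Δ fkh2-dsm and fkh1Δ fkh2-dsm rpd3Δ.

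Counts of changed origins stayed within 1.5 times the main count in 122 of 143 alternatives and in 65 of 74 fits without 1 library. Using only origins with IP over Total above 1.5 left 165 to 195 windows and gave 148 for rpd3Δ/WT (56 up, 92 down), 145 for sir2Δ/WT (45, 100), 101 for sir2Δ rpd3Δ/WT (17, 84), 149 for sir2Δ rpd3Δ/sir2Δ (84, 65) and 97 for their interaction in experiment 1 (91, 6). It gave 89 in rDNA20 strains (20, 69), 70 for the interaction of experiments 1 and 2 (8, 62), 155 for rpd3Δ/WT (35, 120), 179 for fkh/WT (42, 137), 159 for fkhrpd3/WT (22, 137) and 1 for fkhrpd3/fkh (down) in experiment 3, and 72 for its interaction (42, 30). The larger side thereby turned from up to down for rpd3Δ/WT in all 3 experiments, and from lower to higher for the interaction in experiment 3. Background scaling gave 11 in rDNA20 strains, where background took 7.61% and 4.26% of IP counts in the rpd3Δ replicates, and 243 for the interaction in experiment 3; DESeq2 gave 250 for the latter. Windows of 2 kb gave 59 for the interaction of experiments 1 and 2 (33, 26). For fkhrpd3/fkh, with 2 origins in the report, TMM factors gave 8, 10 kb windows 0, a fit of only those groups 4 and DESeq2 30.

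Leaving out 1 library left an arm with 1 sample in experiments 2 and 3, which was assumed to vary like the others. The count in rDNA20 strains then ran from 130 (without WT_rDNA20 replicate 2; 136 without replicate 1) to 288. The interaction of experiments 1 and 2 ran from 40 (without rpd3_rDNA20 replicate 1) to 135, with 52 and 45 without WT_rDNA20 replicates 1 and 2. fkhrpd3/fkh ran from 0 (without fkh replicate 2) to 206 (without fkhrpd3 replicate 2), with 16 without fkhrpd3 replicate 1, and the interaction in experiment 3 from 117 (without fkh replicate 1) to 263 (without fkhrpd3 replicate 1). The other counts moved within 1.5 times. Without the libraries labelled fkh1Δ fkh2-dsm rpd3Δ, rpd3Δ/WT in experiment 3 gave 306, fkh/WT 307 and the interaction of experiments 1 and 2 126.

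No general pairing by replicate number was found. Residuals of different groups with the same number correlated between -0.48 and 0.36 in experiment 1, at -0.16 in experiment 2 and between -0.43 and 0.32 in experiment 3. The best match had the same number in 10 of 36, 0 of 4 and 8 of 24 comparisons. With 2 replicates the residuals of a group mirror each other, so experiments 2 and 3 cannot decide it. In experiment 1, 5 of 18 correlations were above 0.1. Wild type and sir2Δ rpd3Δ gave 0.36, 0.022 and 0.33, so pairing of single groups is not excluded. A fit with a replicate block gave 4 origins for fkhrpd3/fkh and counts within 1.5 times elsewhere.

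Of 144 alternatives for the fixed lists, 28 lost a call, 11 gained one and 5 reversed. With an estimated correlation, which allows origins to vary together, adjusted p = 0.385 for early and centromere and 0.402 for chromosome ends in rpd3Δ/WT of experiment 1, 0.567 for centromere and chromosome ends in sir2Δ/WT, and 0.670 for centromere in sir2Δ rpd3Δ/sir2Δ. It was 0.361 for early, centromere and chromosome ends in rDNA20 strains, and 0.338 for these and 0.269 for late in rpd3Δ/WT of experiment 3. It was 0.620 and 0.157 for centromere and chromosome ends in fkh/WT, 0.698 and 0.288 in fkhrpd3/WT, and 0.569 for early and centromere in fkhrpd3/fkh.

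fry asks another question, and its direction reversed for late in sir2Δ/WT (0.986), centromere in sir2Δ rpd3Δ/WT (0.636), late in sir2Δ rpd3Δ/sir2Δ (0.0781), and late (0.636) and chromosome ends (0.535) in fkhrpd3/fkh. It lost chromosome ends in sir2Δ/WT (0.275), early (0.0846), centromere (0.0845) and chromosome ends (0.144) in rDNA20 strains, centromere in fkhrpd3/WT (0.431), and early and centromere in fkhrpd3/fkh (0.189 each). It gained late in rpd3Δ/WT of experiment 1 (0.000190) and in rDNA20 strains (0.00550), early in sir2Δ rpd3Δ/WT (0.00984) and sir2Δ rpd3Δ/sir2Δ (0.00197), and early and late in fkh/WT (0.00604, 0.00920) and fkhrpd3/WT (0.00218, 0.0178). TMM factors gained early and chromosome ends in sir2Δ rpd3Δ/sir2Δ (0.0404 each) and lost chromosome ends in rpd3Δ/WT of experiment 3 (0.0899). A distance of 10 kb gained chromosome ends in sir2Δ rpd3Δ/sir2Δ (0.0472) and lost centromere in fkhrpd3/WT (0.110).

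For lists from another experiment, an estimated correlation gave adjusted p = 0.256 for the origins that fell or rose in fkh/WT in experiment 1, and 0.406 and 0.0946 in rDNA20 strains. For those that rose or fell in rpd3Δ it gave 0.0946 and 0.164 in rDNA20 strains, 0.0687 for each in rpd3Δ/WT of experiment 3, 0.334 for each in fkh/WT, and 0.860 for the fallen in fkhrpd3/fkh. fry reversed the fkh/WT falls in rpd3Δ/WT of experiment 1 (0.432) and rDNA20 strains (0.527), the fkh/WT rises in sir2Δ rpd3Δ/sir2Δ (0.134) and the rpd3Δ rises in fkhrpd3/fkh (0.530). It gained the fkh/WT falls in sir2Δ rpd3Δ/sir2Δ (6.71e-06) and lost the rpd3Δ falls in rDNA20 strains (0.0629) and fkhrpd3/fkh (0.466) and the rpd3Δ rises in fkh/WT (0.706). Lists called at 0.01 reversed the rpd3Δ rises in fkhrpd3/fkh (0.991).

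With only origins with IP over Total above 1.5, the correlation of rpd3Δ/WT of experiment 1 became 0.87 with sir2Δ rpd3Δ/sir2Δ, 0.93 with rDNA20 strains and 0.29 with fkh/WT. That of rDNA20 strains became 0.88 with rpd3Δ/WT of experiment 3 and 0.27 with fkh/WT, that of sir2Δ rpd3Δ/sir2Δ 0.81 with rDNA20 strains and 0.67 with experiment 3, and that of sir2Δ/WT 0.0321 with fkh/WT.

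The share of IP reads in windows moved with their width by construction. With 2 kb and 10 kb windows the ratio was 0.848 and 0.966 for rpd3Δ/WT of experiment 1, 0.818 and 0.937 for sir2Δ rpd3Δ/WT, 0.771 and 0.954 for sir2Δ rpd3Δ/sir2Δ, 0.695 and 0.873 for rpd3Δ/WT of experiment 3 and 0.602 and 0.827 for fkh/WT. With 10 kb it was 0.757 for fkhrpd3/WT and reversed to 0.982 for sir2Δ/WT. Signal width with an inner limit of 1.5 kb gave ratios of 1.10 for rpd3Δ/WT, 0.908 for sir2Δ/WT, 1.10 for sir2Δ rpd3Δ/WT, 1.21 for sir2Δ rpd3Δ/sir2Δ, 1.12 in rDNA20 strains, and 1.21, 1.30 and 1.39 for rpd3Δ, fkh and fkhrpd3 over WT in experiment 3. Early origin copy number in Total with 2 kb windows was 1.07 times in rDNA20 strains, 1.08 in rpd3Δ, 0.791 in fkh and 0.826 in fkhrpd3. For sir2Δ rpd3Δ/sir2Δ it ran from 0.938 to 1.00 without 1 library, and reversed to 1.00 without sir2 replicate 2.

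Of 2249 alternatives for 198 called values of named origins, 60 lost the call and 20 reversed. Of 990 without 1 library, 34 lost it. Another 36 values of reference origins were not called. Their sign changed in 89 of 580 alternatives, fits without 1 library included. ARS309 and ARS310 in rpd3Δ/WT of experiment 1 became -0.0906 and -0.14 with TMM factors, -0.10 and -0.15 with background scaling and -0.12 and -0.18 with DESeq2. In sir2Δ/WT ARS309 became 0.11 with TMM factors and 0.32 with DESeq2, and with background scaling ARS305 became -0.0321, ARS307 -0.0141, ARS315 -0.50 and ARS606 -0.15. ARS309 in sir2Δ rpd3Δ/WT became -0.26 with background scaling; in sir2Δ rpd3Δ/sir2Δ ARS315 became 0.0418 with 10 kb windows and ARS416 -0.0871 with DESeq2. In fkh/WT background scaling gave ARS307 -0.26, ARS309 -0.34 and ARS522 -0.31; in fkhrpd3/WT ARS522 became -0.41 with it and ARS319 0.39 with TMM factors. Scaling sets the level against which shares are read, which shifts all origins of a comparison alike.

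Of simulated changes 94% to 100% were found at 2-fold and 60% to 92% at 1.5-fold, with rises and falls in balance, which leaves the choice of scaling untried. Alternatives that needed a genome sequence (motifs at other distances), a signal in place of counts (pseudocounts) or mitochondrial bins as the denominator of the array could not be run.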

Other observations

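The values below belong to no comparison that was planned, and all were looked at after the results above were seen.

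The silent mating-type loci took little BrdU. IP counts per bin at HML stood at 0.0492 ± 0.00292 times the genome mean in wild type, 0.0322 ± 0.01003 in rpd3Δ, 0.0995 ± 0.0509 in sir2Δ and 0.0992 ± 0.0407 in sir2Δ rpd3Δ (SD, n = 3), and at HMR at 0.0767 ± 0.0122, 0.0507 ± 0.00650, 0.139 ± 0.0238 and 0.0854 ± 0.0319. In fkh1Δ fkh2-dsm HML stood at 0.0993 ± 0.00616, against 0.0201 ± 0.00180 in wild type at 90 min (n = 2), and HMR at 0.116 ± 0.0282 against 0.0815 ± 0.0341, where replicates overlapped. IP counts per bin in background bins were at 0.137 ± 0.0356 times the genome mean in sir2Δ against 0.0790 ± 0.00341 in wild type (n = 3), and at 0.146 ± 0.00714 in fkh1Δ fkh2-dsm against 0.0732 ± 0.00617 in wild type at 90 min (n = 2). In rpd3Δ background stood at 0.0979 ± 0.00256 in experiment 1 (n = 3) and at 0.155 ± 0.00261 at 90 min (n = 2), where HML was at 0.0310 ± 0.00317 and HMR at 0.0676 ± 0.000224.

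Strains differed in copy number outside the named loci. CUP1-1 (VIII 212535 to 212720), a metallothionein gene in a tandem array, stood at 6.84 ± 0.949 and 6.45 ± 0.505 times the genome median in Total of the rDNA20 wild type and rpd3Δ, and at 6.87 ± 0.398 and 6.63 ± 0.341 in wild type and rpd3Δ at 90 min (SD, n = 2). In fkh1Δ fkh2-dsm it was 2.08 ± 0.0580 and in the libraries labelled fkh1Δ fkh2-dsm rpd3Δ 1.83 ± 0.0372 (n = 2), and in experiment 1 it lay between 2.40 and 2.88. RRN11 (XIII 190244 to 191767), a gene for a ribosomal RNA transcription factor, stood at 1.96 ± 0.261 and its neighbour CAT2 at 2.12 ± 0.0539 in the rDNA20 wild type, against 0.956 ± 0.0926 and 1.04 in its rpd3Δ strain. URA3 stood at 2.08 in wild type, 1.98 in rpd3Δ, 1.04 in sir2Δ and 1.07 in sir2Δ rpd3Δ of experiment 1, at 4.20 and 3.70 in the rDNA20 strains, and between 1.99 and 2.10 in experiment 3. TRP1 stood at 1.61, 1.33, 1.84 and 2.10 in wild type, rpd3Δ, sir2Δ and sir2Δ rpd3Δ of experiment 1. TRP1 lies beside ARS416 and Total also carries replicated DNA, so its values need not be strain differences in copy number.

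In Total of fkh1Δ fkh2-dsm, the RPD3 flanks stood at 1.60 and 1.69 times the genome median in replicate 2 and at 1.09 and 0.967 in replicate 1. In wild type at 90 min they lay between 0.846 and 1.07.

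Replicate libraries differed by more than counting error. Chi-square per degree of freedom between a pair ran from 1.08 for Total of fkh1Δ fkh2-dsm to 33.3 for IP of rpd3Δ rDNA20. The next highest was IP of the libraries labelled fkh1Δ fkh2-dsm rpd3Δ.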
